A study of Homo sapiens with 8 samples.

How the data were processed

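RNA of Karpas299 cells was measured on 8 Illumina HumanHT-12 v3 expression arrays, 2 biological duplicates in each of 4 groups. The groups, taken from the sample titles, were untreated cells, cells given CD153-Fc, cells given the antibody T104, and cells given both. Per the labels' protocols, RNA was extracted with TRI reagent, checked on a Bioanalyser and copied into biotin-labelled cRNA with the Ambion MessageAmp kit.

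The authors deposited a table of probe intensities on a linear scale that had not been normalized, with a detection p-value for each probe and array. That p-value ranks a probe's intensity among the array's negative control probes, whose own values were not used here. The authors also deposited a table of processed intensities on a linear scale. The series design names BeadStudio and the submitters' processing notes name GenomeStudio, with versions not given in the sources used here. The processed intensities had column medians of 119.697 and 119.712 in untreated replicates 1 and 2, 119.685 and 119.695 with CD153-Fc, 119.704 and 119.694 with T104, and 119.692 and 119.717 with both. Their log2 values correlated with those of the unprocessed intensities at r of at least 0.999553 on each array, so their scale was linear, and they were not centred. Direction has no meaning for single-colour arrays. How the authors made these values equal in median is not given in the sources used here, and they served as an alternative only.

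Each array held 48797 probes. Mean intensity ran from 722 to 850 and the number of probes detected at a detection p under 0.01 from 10713 to 12967. The number of arrays, 2 per group, limits the precision. The main values were made with limma 3.58.1 in R 4.3.3 by the neqc function, which estimated the background from the detection p-values, added an offset of 16, normalized arrays by quantiles and took log2. Probes detected on at least 2 of the 8 arrays, whatever their group, were kept, which left 12543. Probe names came from the platform's annotation table, with symbols updated through a RefSeq gene table of assembly GRCh38.p14 that was used for names only. That table gave 28093 probes 1 symbol, 13 several and 20691 none. No gene was named from a probe with several symbols or none. The brightest kept probe stood for each gene, and an unnamed probe stood for itself, giving 10183 features, of which 8509 were named genes and 1674 unnamed probes. Among called genes with more than 1 kept probe, another probe was called in the opposite direction for 3 genes in T104 against untreated (CCR6, CREB1 and RAB3IP) and for 0 genes in each other comparison.

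All 8 arrays entered a limma model with a mean per group and no other term, so that one estimate of the spread with 4 residual degrees of freedom was shared. The eBayes step used a trend with intensity, which added 8.78 prior degrees of freedom. There were 7 contrasts. Each treated group was set against untreated cells, T104 against CD153-Fc, the combination against each single agent, and the interaction was the response to both minus the sum of the responses to each. Adjusted p-values follow Benjamini and Hochberg over the 10183 features of a contrast, and a call needs an adjusted p under 0.05. Changes are differences of log2 intensity with the standard error (SE) of the model and 2 arrays per group. The shared spread averages over the groups, although the untreated duplicates differed more (SD of the difference 0.45 log2 against 0.23 to 0.26 in treated groups). SEs and p-values may therefore be too small against untreated cells and too large between treated groups. Where a probe was below the detection limit on both arrays of a group, the fold is given as "at least", the brighter group's mean over the higher of the lowest detected signal and the probe's own signal on each array of the dimmer group.

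Named genes were chosen by a fixed rule. Against untreated cells, they were the 10 largest rises and 10 largest falls among named genes past an adjusted p of 0.05 whose arrays did not overlap between groups. The other contrasts took 5 and 5, or the 3 smallest p-values where none passed. From each gene list came up to 4 members with the largest change with CD153-Fc and up to 2 with the largest change with T104, and TNFRSF8, ALK, NFKB2, TRAF1, CDKN1A and MYC were always included. Members outside this rule, named where 5 or fewer members of a list had changed, were chosen after their values were seen. This rule, the groups, the contrasts and their tests, the gene lists and all alternatives but 1 were fixed before the data were examined. Not in that plan were the fry tests over the features raised by CD153-Fc and the slope of the combination on T104, whose sets were chosen on these data.

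There were 30 gene lists with 847 different genes, of which 790 had a probe and 568 were tested. They covered NF-kB feedback and targets, CD30 receptor-proximal signalling, cytokines and chemokines, their receptors, the TNF receptor superfamily and its ligands, anti-apoptotic and pro-apoptotic genes, p53 targets and CDK inhibitors, G1/S and DNA replication, G2/M and mitosis, MYC and its targets, AP-1 and immediate early genes, and MAPK feedback genes. They also covered ALK and STAT3 associated genes of anaplastic large cell lymphoma, T cell identity, cytotoxic granules, interferon-stimulated genes, MHC class I and MHC class II with co-stimulation, adhesion and migration, cholesterol synthesis, glycolysis and hypoxia, the unfolded protein response, heat shock and oxidative stress. Markers of B cells, of myeloid cells and of fibroblasts and epithelium, cytosolic ribosomal proteins and oxidative phosphorylation completed them. Lists were tested against the other genes with limma's camera at a preset correlation between genes of 0.01, adjusted over the 30 lists of a contrast, and again with an estimated correlation. The fry test, which asks whether a list's genes moved one way without comparing them with other genes, was run beside it. Of 210 pairs of a list and a contrast, 67 were called with the preset correlation and 5 with an estimated one. In all 67 the median, the mean and the test had the same sign, and in 33 of the others they differed.

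The correlation of the CD153-Fc and T104 changes was set beside 100 simulations of unchanged groups that shared their controls. Alternatives were 1 change at a time to the background step, the scaling between arrays, the probe filter, the handling of several probes, the variance prior, array weights, the arrays in the model and the processed table, a term for the replicate number, and the omission of each array in turn. An array was left out only for contrasts that used its group. Median scaling over the kept probes was added after the data were seen. A term for the array's slide was not run, because no slide was used here as a label. The pipeline was tested on simulated data for CD153-Fc against untreated with 10183 features, with 50 genes changed at each of 4 sizes. It recovered 22% of the changes of 0.5 log2, 90% of those of 1 log2, and 100% of those of 1.5 and of 2 log2. Of 167 calls, 11 were false, or 6.59%. The simulation gave all groups the same spread. The real untreated duplicates differed more, with an SD of the difference of 0.45 log2 against 0.24 with CD153-Fc. These rates therefore need not hold for the real comparison.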

Results

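Gene expression was measured in Karpas299 cells, an established human line of anaplastic large cell lymphoma of T cell origin that carries CD30 on its surface and an NPM1-ALK fusion kinase. CD30, encoded by TNFRSF8, is a member of the tumour necrosis factor (TNF) receptor superfamily, and CD153 is its natural ligand. Cells were cultured for 16 h and then kept for 8 h in that medium without treatment, with CD153 fused to an antibody Fc part (CD153-Fc, 10 µg/ml), with the agonistic anti-CD30 antibody T104 (10 µg/ml), or with 10 µg/ml of each. The question was how the response to the natural ligand compares with that to the antibody. Each of the 4 groups had 2 biological duplicates. No group was given an Fc part alone or a control antibody. Effects of the Fc part or of added protein therefore cannot be told apart from those of binding CD30.

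Between 10713 and 12967 of the 48797 probes were detected per array, and mean intensity lay between 722 and 850. Replicates correlated across features at r = 0.993 with CD153-Fc, 0.994 with T104 and 0.992 with both agents, and at r = 0.977 in untreated cells. Untreated replicate 2 correlated more closely with the CD153-Fc arrays (r = 0.987 and 0.986) and the combination arrays (0.978 and 0.979) than with its duplicate. With the T104 arrays it correlated less closely (0.974 and 0.973). This disagreement of the controls limits every comparison with untreated cells. The SD of the difference between duplicates was 0.45 log2 in untreated cells against 0.24, 0.23 and 0.26 in the treated groups. Untreated replicate 1 lay at -40.2 on the first principal component, which held 51.9% of the variance, and untreated replicate 2 at -18.6. The CD153-Fc arrays lay at -0.60 and -0.0080, the T104 arrays at 16.9 and 17.1, and the arrays with both agents at 14.0 and 11.5.

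The receptor's own transcript could not be followed. The TNFRSF8 probe was detected on 1 of 2 untreated arrays, 1 of 2 CD153-Fc arrays and 0 arrays of the groups with T104, so its change of 0.48 ± 0.25 log2 (SE) with CD153-Fc was a value near background and its level with T104 was not above background. ALK, the kinase part of the fusion, was bright in all groups and was not called with CD153-Fc (0.11 ± 0.15 log2) or T104 (0.22 ± 0.15), with -0.07 and 0.04 without untreated replicate 1. MYC, a driver of cell growth, was not called either (-0.09 ± 0.14 and -0.39 ± 0.14), although ALK and MYC were called with T104 without untreated replicate 2.

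The comparison of CD153-Fc with untreated cells asked what the natural ligand does. CXCL8, which encodes a neutrophil-attracting chemokine, rose the most of the named genes, by 3.89 ± 0.19 log2 or 14.8-fold (adjusted p = 2.05e-07 by limma with Benjamini-Hochberg adjustment, n = 2 arrays per group). IL4I1, a secreted amino acid oxidase, and TNFRSF9, the co-stimulatory receptor 4-1BB, were not detected in untreated cells and rose at least 3.17-fold and 2.58-fold. CXCR4, the receptor of CXCL12, rose by 2.65 ± 0.21 log2, TRAF1, an adaptor of TNF receptors, by 2.64 ± 0.17, and CD83, an activation marker of antigen-presenting cells and lymphocytes, by 2.48 ± 0.15. DRAM1, a regulator of autophagy, rose by 2.45 ± 0.16 log2, RGS1, a brake on G protein signalling, by 2.40 ± 0.17, the gene of lymphotoxin beta (LTB) by 2.32 ± 0.20 and the NF-kB subunit gene RELB by 2.11 ± 0.18. The falls were smaller. GPRIN3 was at least 1.58-fold lower, and SMIM43 (-1.16 ± 0.23 log2), the polycomb-related MBTD1 (-1.08 ± 0.24), the zinc finger gene ZNF69 (-1.08 ± 0.17) and SGSM1 (-1.01 ± 0.19) also fell. TRMT6, part of a tRNA methyltransferase (-0.96 ± 0.22 log2), the Src family kinase gene BLK (-0.87 ± 0.19), TMEM17 (-0.87 ± 0.17), ZNF394 (-0.85 ± 0.19) and the centrosomal gene CEP19 (-0.85 ± 0.18) were lower too. Each of these 10 falls lost its call in at least 1 other setting and without at least 2 of the arrays. The 10 rises kept theirs in every setting that tested them and with each array left out. IL4I1 and TNFRSF9, not detected in untreated cells, were not tested where probes had to be detected on every array.

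Among 27 tested genes of NF-kB feedback and targets, 16 rose with CD153-Fc and 11 did not pass, and 20 rose when adjusted over the list alone. NFKB2, the precursor of the p52 subunit, rose by 1.97 ± 0.25 log2, IER3, an early response gene, by 1.84 ± 0.23, and the mitochondrial superoxide dismutase gene SOD2 by 1.44 ± 0.16. The list was called higher (median 1.05 log2, camera adjusted p = 7.81e-29) and held with an estimated correlation (adjusted p = 0.0300). In untreated replicate 1 the median member lay at -0.21 log2 relative to untreated replicate 2. Of 14 tested genes of CD30 receptor-proximal signalling, 4 rose, also when adjusted over the list alone: TRAF1, the deubiquitinase gene CYLD (1.05 ± 0.21 log2), TRAF3 (0.82 ± 0.17) and TANK (0.70 ± 0.14), the last 3 of which lost their calls in other settings (CYLD at 0.69 without background correction). That list was called higher (adjusted p = 3.75e-04), with adjusted p = 0.0981 with an estimated correlation.

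Of 16 tested cytokine and chemokine genes, 7 rose with CD153-Fc and 11 when adjusted over the list alone. Besides CXCL8 and LTB, these included EBI3, a subunit of interleukins 27 and 35 (at least 2.10-fold), and TNF (1.37 ± 0.18 log2). The list was called (adjusted p = 1.88e-10), but adjusted p = 0.0733 with an estimated correlation, and its median member lay at -0.23 log2 in untreated replicate 1 relative to replicate 2. Of 21 cytokine and chemokine receptors, 5 rose, and 10 rose and 1 fell when adjusted over the list alone. IL21R rose by 1.46 ± 0.23 log2 and CCR7, a lymph node homing receptor, by 1.07 ± 0.17, though both calls, like that of TNF, were lost in 1 other setting. This list was called as well (adjusted p = 2.15e-05, and adjusted p = 0.214 with an estimated correlation). The TNF receptor superfamily and its ligands had 4 rises among 17 genes, 7 when adjusted over the list alone, with the co-stimulatory ligand gene CD70 at 1.38 ± 0.16 log2 (adjusted p = 4.70e-06, and adjusted p = 0.0733 with an estimated correlation).

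In CD153-Fc against untreated cells, 140 features were called, 112 higher and 28 lower, and 68 rises and 7 falls were at least 2-fold. Median scaling in place of quantile normalization gave 90 calls, 57 higher and 33 lower, and the model of these 2 groups alone gave 33, all higher. The count was 268 without untreated replicate 1, 2624 without untreated replicate 2, 44 without CD153-Fc replicate 1 and 37 without CD153-Fc replicate 2.

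The comparison of T104 with untreated cells asked the same of the antibody. CXCL8 rose by 6.37 ± 0.19 log2, or 83.0-fold (adjusted p = 5.77e-10). CCND2, which encodes the G1 cyclin D2, rose at least 9.84-fold from below the detection limit, as did TNFRSF9 (at least 10.0-fold) and IL4I1 (at least 9.76-fold). RGS1 rose by 4.11 ± 0.17 log2, DRAM1 by 3.81 ± 0.16, TRAF1 by 3.75 ± 0.17, CD83 by 3.48 ± 0.15 and LTB by 3.38 ± 0.20, and LTA, the gene of lymphotoxin alpha, rose at least 4.69-fold. KLHL14 was at least 2.05-fold lower and PTPN22, which encodes a phosphatase that restrains T cell receptor signalling, at least 1.74-fold lower. RAB27B, a GTPase of secretory vesicles (-2.23 ± 0.23 log2), KANK1 (-2.03 ± 0.30), TNFRSF19 (-1.96 ± 0.16) and BLK (-1.86 ± 0.19) also fell, and SMIM43, ASB13, GPRIN3 and TTLL11 were at least 2.48-fold, 1.81-fold, 1.20-fold and 1.94-fold lower. TTLL11 lost its call without each of 2 arrays. The other 19 named changes kept theirs in every setting that tested them and with each array left out. Genes given as "at least" a fold were not tested where probes had to be detected on every array.

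With T104, 22 of the 27 NF-kB genes rose, 24 when adjusted over the list alone. NFKB2 rose by 2.80 ± 0.25 log2, SOD2 by 3.18 ± 0.16 and RELB by 2.54 ± 0.18. The list's median was 1.56 log2 (adjusted p = 1.12e-29) and its call held with an estimated correlation (adjusted p = 0.0283). In CD30 receptor-proximal signalling, 7 of 14 genes rose and 1 fell, also when adjusted over the list alone. BIRC2, which encodes an inhibitor of apoptosis that binds TRAF proteins, rose by 1.35 ± 0.19 log2 and TRAF3 by 1.23 ± 0.17, and the gene that fell was the kinase gene MAP3K5 (at least 1.51-fold lower). The list's adjusted p = 4.00e-05 became adjusted p = 0.0593 with an estimated correlation.

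Of the 16 cytokine and chemokine genes, 12 rose with T104 and 2 fell, 12 and 4 when adjusted over the list alone. EBI3 rose at least 6.24-fold, the gene of interleukin 17F (IL17F) at least 3.38-fold, and the chemokine gene CCL20 by 3.06 ± 0.23 log2, while IL10 (-0.54 ± 0.15) and IL26 (-0.83 ± 0.21) fell. The call (adjusted p = 2.30e-11) was lost with an estimated correlation (adjusted p = 0.0593). Of the receptors, 9 rose and 1 fell, 11 and 2 when adjusted over the list alone, with CXCR4 at 3.01 ± 0.21 log2 and CCR7 at 1.69 ± 0.17 (adjusted p = 4.00e-05, and adjusted p = 0.193 with an estimated correlation). The receptor that fell was CCR6 (-0.37 ± 0.11), of which another probe was called higher. The TNF receptor superfamily and ligands had 7 rises among 17 genes, and 8 rises and 2 falls when adjusted over the list alone (adjusted p = 2.04e-05, and adjusted p = 0.0593 with an estimated correlation).

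Of 43 G1/S and replication genes, 2 rose and 2 fell with T104, the same numbers when adjusted over the list alone, and the list was not called (adjusted p = 0.531). The rises were CCND2 and its partner kinase gene CDK6 (1.23 ± 0.18 log2), and the falls E2F2 (-0.84 ± 0.24) and ORC6 (-0.44 ± 0.10). CDK6 alone of these passed with CD153-Fc (1.04 ± 0.18), and CCND2 was not above background in untreated cells or with CD153-Fc. Of 40 G2/M genes, 0 passed in the 3 comparisons with untreated cells, over all features or adjusted over the list alone, with 1, 5 and 4 genes at an unadjusted p under 0.05 in limma for CD153-Fc, T104 and both, and fry adjusted p = 0.514, 0.0841 and 0.0854. NUF2, a kinetochore gene, had the largest change with T104 among them (-0.86 ± 0.32, adjusted p = 0.107, and -0.32 without untreated replicate 1). Of 33 genes of the MYC list, 1 fell with T104 (the spermidine synthase gene SRM, -0.54 ± 0.15). With CD153-Fc and both agents 0 passed in limma, with 5 and 6 at an unadjusted p under 0.05, and 0 passed in these 3 comparisons when adjusted over the list alone. Camera did not call the MYC list (adjusted p = 0.376, 0.409 and 0.102), and fry, which does not compare it with other genes, placed it lower (adjusted p = 0.0232, 0.00596 and 0.00350). Of 16 p53 targets and CDK inhibitors, 4 rose and 1 fell with T104, 5 and 2 when adjusted over the list alone. CDKN1A, the gene of the CDK inhibitor p21, rose by 2.23 ± 0.32 log2 and the stress response gene GADD45A by 2.61 ± 0.14, and XPC fell by 0.62 ± 0.18. The list was called (adjusted p = 7.00e-04), with adjusted p = 0.130 with an estimated correlation. With CD153-Fc, GADD45A alone rose (1.27 ± 0.14), CDKN1A was at 0.88 ± 0.32 (adjusted p = 0.218), and the list was called at adjusted p = 0.0410 (adjusted p = 0.357 with an estimated correlation). The untreated arrays differed in CDKN1A, with 7.35 log2 in replicate 1 and 8.65 in replicate 2.

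Of 9 anti-apoptotic genes, 2 rose with T104 and 4 when adjusted over the list alone. These were BIRC2 and CFLAR, the gene of the caspase-8 inhibitor c-FLIP (0.88 ± 0.15 log2), and the list was not called (adjusted p = 0.0531). Of 14 pro-apoptotic genes, 3 rose and 1 fell, 4 and 3 when adjusted over the list alone, and the list was not called (adjusted p = 0.409). PMAIP1, the BH3-only gene NOXA, rose by 0.98 ± 0.19 log2, HTRA2 by 0.85 ± 0.15 and TRADD by 0.74 ± 0.16, and CASP6 fell by 0.82 ± 0.18. With CD153-Fc, 0 genes of these lists passed in limma, with 0 anti-apoptotic and 3 pro-apoptotic genes at an unadjusted p under 0.05 (fry adjusted p = 0.298 and 0.0304), and adjusted over the list alone 0 and 2 rose. The median anti-apoptotic gene lay at 0.30 log2 in untreated replicate 1 relative to replicate 2.

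Of 19 AP-1 and immediate early genes, 7 rose and 2 fell with T104, also when adjusted over the list alone. ATF3 rose by 1.80 ± 0.17 log2, BATF by 1.48 ± 0.17 and JUN by 1.22 ± 0.20, and FOS (-0.95 ± 0.24) and ID3 (-0.83 ± 0.15) fell (adjusted p = 0.00309, and adjusted p = 0.105 with an estimated correlation). With CD153-Fc, JUN (0.98 ± 0.20) and BATF (0.86 ± 0.17) rose, though by 0.64 and 0.56 without untreated replicate 1. Their calls were lost in 4 and 3 other settings. Adjusted over the list alone 5 rose and 1 fell (list adjusted p = 0.0253, and adjusted p = 0.166 with an estimated correlation). Of 12 MAPK feedback genes, 6 rose with T104, also when adjusted over the list alone, among them IER3 (2.51 ± 0.23) and the phosphatase gene DUSP1 (1.89 ± 0.21), with adjusted p = 0.00309 and adjusted p = 0.105 with an estimated correlation. IER3 alone rose with CD153-Fc, 3 genes when adjusted over the list alone (adjusted p = 0.0204, and adjusted p = 0.166 with an estimated correlation). Of 28 genes tied to ALK and STAT3 in this lymphoma, 4 rose with CD153-Fc and 8 when adjusted over the list alone. These were CD274, the checkpoint ligand PD-L1 (1.29 ± 0.22 log2), the interleukin 2 receptor alpha gene IL2RA (0.82 ± 0.16), MUC1 (0.81 ± 0.17) and IL22 (0.77 ± 0.16), each of which lost its call in other settings. With T104, 10 rose and 1 fell, 13 and 1 when adjusted over the list alone, with CD274 at 1.81 ± 0.22, and IL10 was the gene that fell. The list was called with CD153-Fc (adjusted p = 0.00307, and adjusted p = 0.109 with an estimated correlation) and T104 (adjusted p = 2.07e-04, and adjusted p = 0.0593 with an estimated correlation).

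Of 13 T cell identity genes, 2 rose and 3 fell with T104, 3 and 4 when adjusted over the list alone (list adjusted p = 0.896). RUNX3 rose by 0.90 ± 0.18 log2 and CD5 at least 1.58-fold, while PTPN22, PTPN6 (-0.99 ± 0.20) and CD4 (-0.68 ± 0.19) fell. With CD153-Fc 0 of the T cell genes passed in limma, with 4 at an unadjusted p under 0.05 (fry adjusted p = 0.794), and 1 rose when adjusted over the list alone. Of 12 cytotoxic granule genes, CST7, a cystatin, alone fell with T104 (-0.83 ± 0.16), with 1 rise and 2 falls when adjusted over the list alone (list adjusted p = 0.918). With CD153-Fc 0 of the granule genes passed, 1 was at an unadjusted p under 0.05 (fry adjusted p = 0.514), and 1 fell when adjusted over the list alone. Of 33 interferon-stimulated genes, 1 rose with CD153-Fc and 6 when adjusted over the list alone, and 6 rose and 2 fell with T104, also when adjusted over the list alone (list adjusted p = 0.200 and 0.457). ISG20 rose by 0.87 ± 0.17 with CD153-Fc, a call lost in 4 other settings, and by 1.48 ± 0.17 with T104. The guanylate-binding protein gene GBP4 rose by 1.59 ± 0.27 with T104, while MX1 (-0.60 ± 0.13) and MX2 (-0.86 ± 0.18) fell. The median member of this list lay at -0.26 log2 in untreated replicate 1 relative to replicate 2. Of 18 MHC class I genes, ERAP2, an aminopeptidase gene, fell with T104 (-0.77 ± 0.18, and -0.51 without untreated replicate 1) and 0 passed with CD153-Fc, also when adjusted over the list alone (list adjusted p = 0.374 and 0.692). With CD153-Fc 3 of the class I genes were at an unadjusted p under 0.05 (fry adjusted p = 0.335). Of 12 MHC class II and co-stimulation genes, CD83 and CD274 rose with CD153-Fc and with T104, also when adjusted over the list alone (list adjusted p = 0.147 and 0.315), and the median member lay at -0.32 log2 in untreated replicate 1 relative to replicate 2.

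Markers of other cells were few. Of 15 B cell markers, 2 were tested, and both, BLK and EBF1 (-0.69 ± 0.19), fell with T104, also when adjusted over the list alone, which the list test called (adjusted p = 0.00393, and adjusted p = 0.105 with an estimated correlation). With CD153-Fc, BLK fell, both passed when adjusted over the list alone, and the list had adjusted p = 0.00767 (adjusted p = 0.166 with an estimated correlation). Of 4 tested myeloid markers 0 passed in the 3 comparisons with untreated cells, also when adjusted over the list alone, with 1, 2 and 1 at an unadjusted p under 0.05 (fry adjusted p = 0.136, 0.0896 and 0.132). S100A8, a calcium-binding protein gene of myeloid cells, was at 0.69 ± 0.24 with T104 (adjusted p = 0.0949, and called at 0.84 without untreated replicate 1). Of 3 fibroblast and epithelial markers, MUC1 rose with CD153-Fc (1 rise and 1 fall when adjusted over the list alone) and with T104 (0.97 ± 0.17), and COL6A3 fell with T104 (-0.81 ± 0.15), 2 rises and 1 fall when adjusted over the list alone (list adjusted p = 0.676 and 0.431). The median of these 3 lay at -0.47 log2 in untreated replicate 1 relative to replicate 2. Of 39 ribosomal protein genes, RPL37 fell with T104 (-0.83 ± 0.19), also when adjusted over the list alone, and of 36 oxidative phosphorylation genes NDUFB10 fell (-0.53 ± 0.15), with 0 when adjusted over the list alone. In these lists 0 genes passed in limma with CD153-Fc (5 ribosomal and 6 oxidative phosphorylation genes at an unadjusted p under 0.05, fry adjusted p = 0.514 and 0.117) or with both agents (3 and 2 genes, fry adjusted p = 0.239 and 0.170). Neither list was called with T104 (adjusted p = 0.562 and 0.409).

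In T104 against untreated cells, 1071 features were called, 520 higher and 551 lower, and 216 rises and 147 falls were at least 2-fold. Median scaling gave 317 higher and 910 lower. It used all 48797 probes, most of them undetected, and placed the features' median change at -0.19 log2 with CD153-Fc, -0.20 with T104 and -0.31 with both. Over the kept probes alone, median scaling placed it at -0.0067, -0.0104 and 0.00999, with 561 features higher and 580 lower with T104. The lower medians thus depended on the probes used for scaling. The quantile normalization used for all changes given here sets each array to one distribution. The count was 3419 without untreated replicate 2, 351 without T104 replicate 1 and 286 without T104 replicate 2, and 399 in a model of these 2 groups alone. CD5, EBF1, ERAP2, RPL37 and NDUFB10 lost their calls in at least 1 setting other than leaving out an array.

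**Figure D1:**
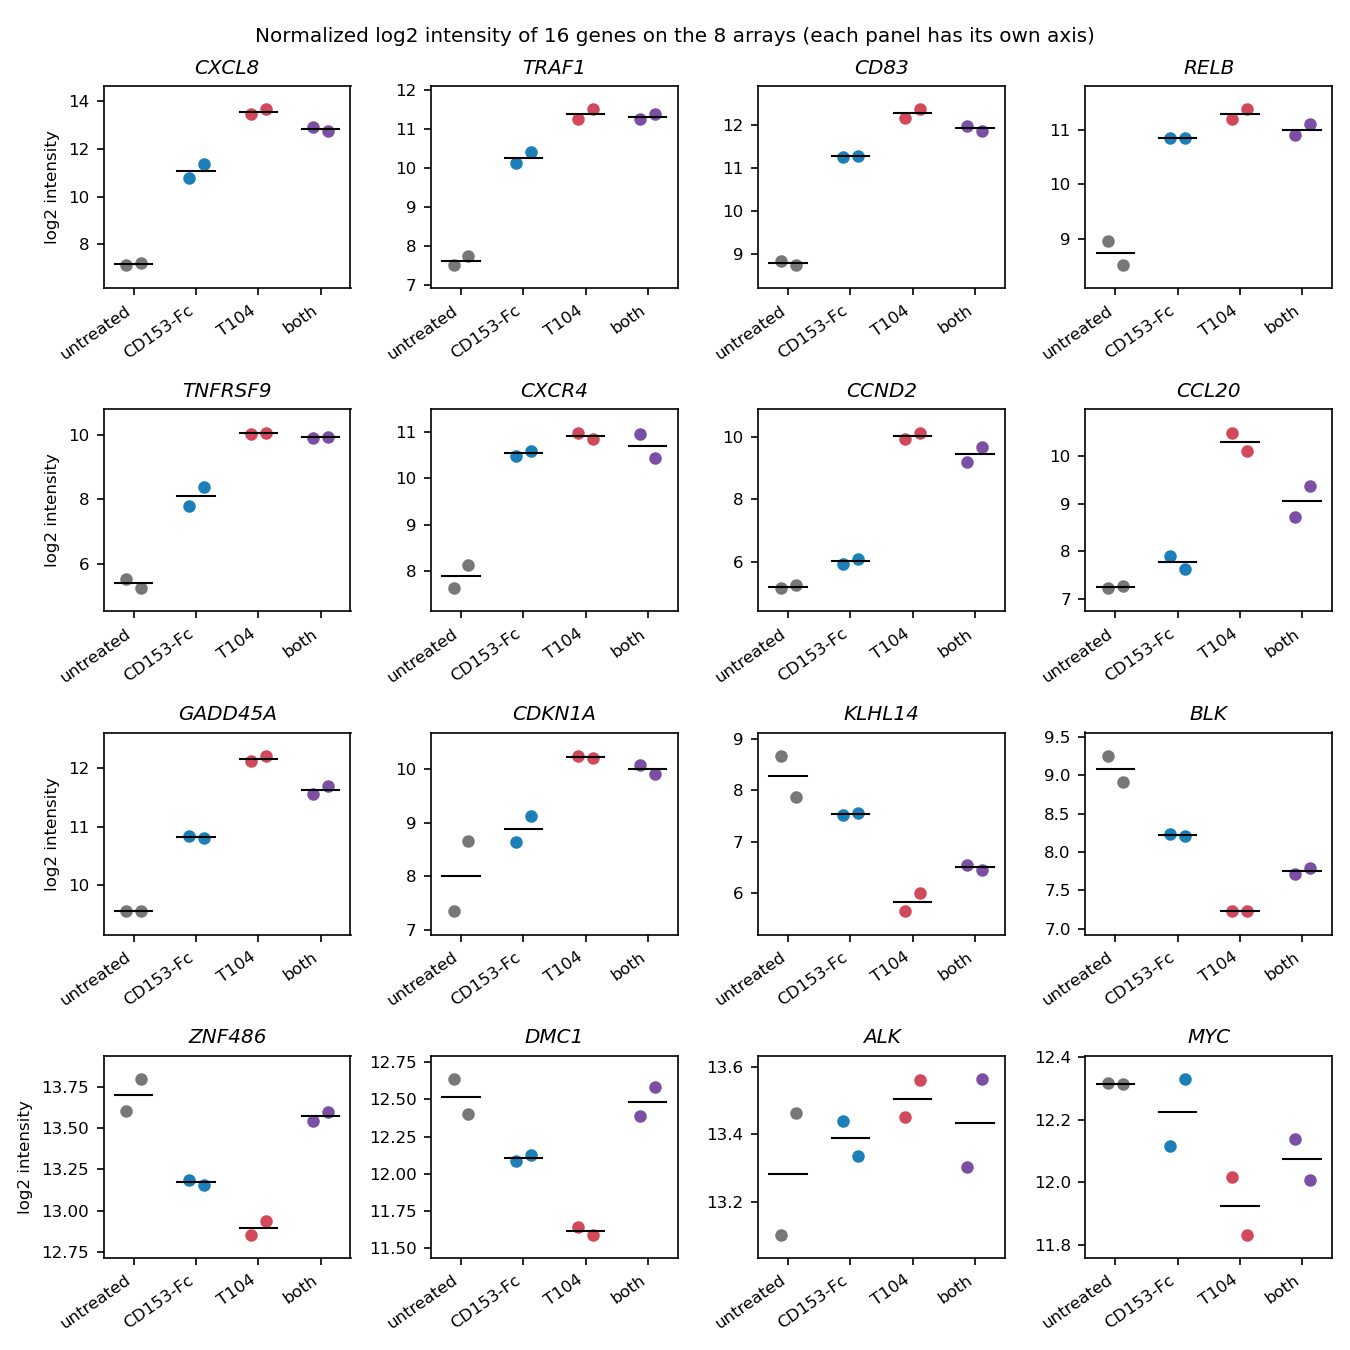
Normalized log2 intensity of 16 named genes, one panel each with its own vertical axis, for the 4 groups on the horizontal axis. Points are the 2 arrays of a group and lines are group means. CXCL8 lay at a mean of 7.18 in untreated cells, 11.1 with CD153-Fc, 13.6 with T104 and 12.8 with both.

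With both agents, the question was whether the combination differed from each agent. CXCL8 rose by 5.65 ± 0.19 log2 against untreated cells, or 50.2-fold (adjusted p = 3.34e-09). TNFRSF9 rose at least 9.23-fold, IL4I1 at least 7.68-fold, CCND2 at least 6.54-fold and EBI3 at least 5.78-fold. TRAF1 rose by 3.69 ± 0.17 log2, RGS1 by 3.65 ± 0.17, DRAM1 by 3.35 ± 0.16, LTB by 3.21 ± 0.20 and CD83 by 3.13 ± 0.15. SLC9A9, an endosomal sodium-proton exchanger gene, was at least 1.45-fold lower, the keratin gene KRT80 1.11-fold, PTPN22 1.51-fold, SMIM43 2.15-fold, KLHL14 1.78-fold, GPRIN3 1.04-fold, PHTF1 1.39-fold and the homeobox gene DMBX1 2.78-fold. KANK1 (-1.80 ± 0.30 log2) and RAB27B (-1.64 ± 0.23) fell as well. PHTF1 and KANK1 each lost the call without 1 of the arrays, and PHTF1 in 1 other setting.

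Of the 27 NF-kB genes, 21 rose with both agents, 22 when adjusted over the list alone, with NFKB2 at 2.50 ± 0.25 log2 and RELB at 2.26 ± 0.18 (median 1.21 log2, adjusted p = 5.65e-28, and adjusted p = 0.0318 with an estimated correlation). In CD30 receptor-proximal signalling 5 rose, and 5 rose and 1 fell when adjusted over the list alone, with TRAF3 at 1.27 ± 0.17 (adjusted p = 3.94e-05, and adjusted p = 0.0652 with an estimated correlation). Of the cytokine and chemokine genes 11 rose, and 12 rose and 1 fell when adjusted over the list alone, with CCL20 at 1.80 ± 0.23 (adjusted p = 6.57e-14, and adjusted p = 0.0502 with an estimated correlation). Of their receptors 8 rose, 12 when adjusted over the list alone (adjusted p = 1.02e-06, and adjusted p = 0.150 with an estimated correlation), and of the TNF receptor superfamily and ligands 8 rose, also when adjusted over the list alone (adjusted p = 1.58e-06, and adjusted p = 0.0502 with an estimated correlation). CDKN1A rose by 2.00 ± 0.32 log2 and GADD45A by 2.07 ± 0.14 among 4 rises of the p53 list (adjusted p = 0.0202, and adjusted p = 0.254 with an estimated correlation). The count was 679 features, 389 higher and 290 lower, and 180 rises and 88 falls were at least 2-fold. Median scaling gave 1638, 210 higher and 1428 lower, array weights 378, and a model of these 2 groups alone 180. Over the kept probes alone, median scaling gave 710, 421 higher and 289 lower. Without untreated replicate 2 the count was 3345, without replicate 1 of the combination 188 and without its replicate 2 219.

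**Figure D2:**
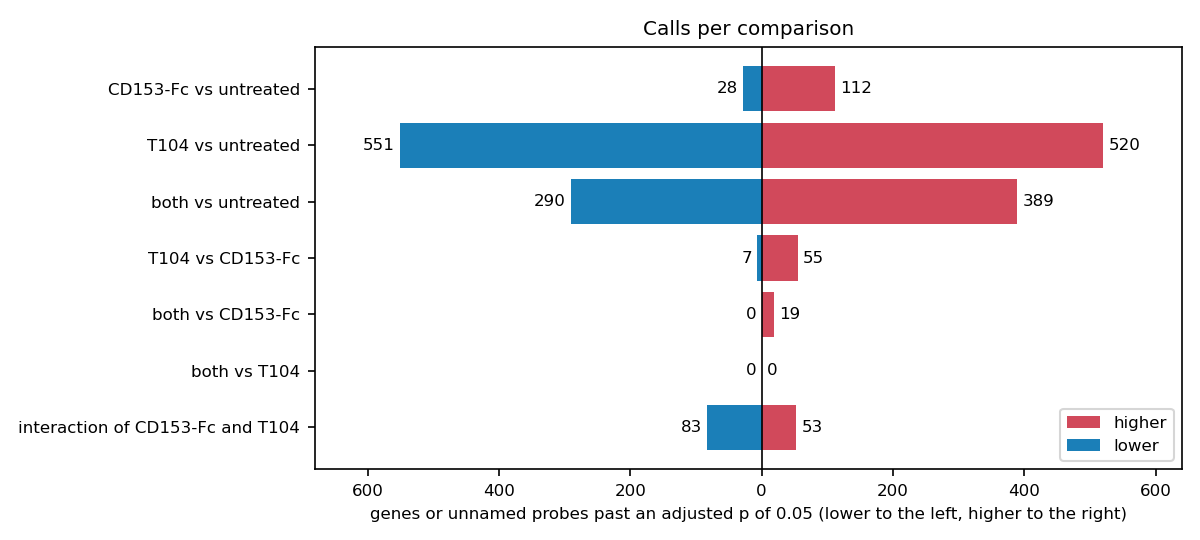
Number of features called higher and lower in each comparison (horizontal bars from 0, limma with an adjusted p under 0.05). The bars run from 0 calls for both agents against T104 to 1071 calls for T104 against untreated cells.

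**Figure D3:**
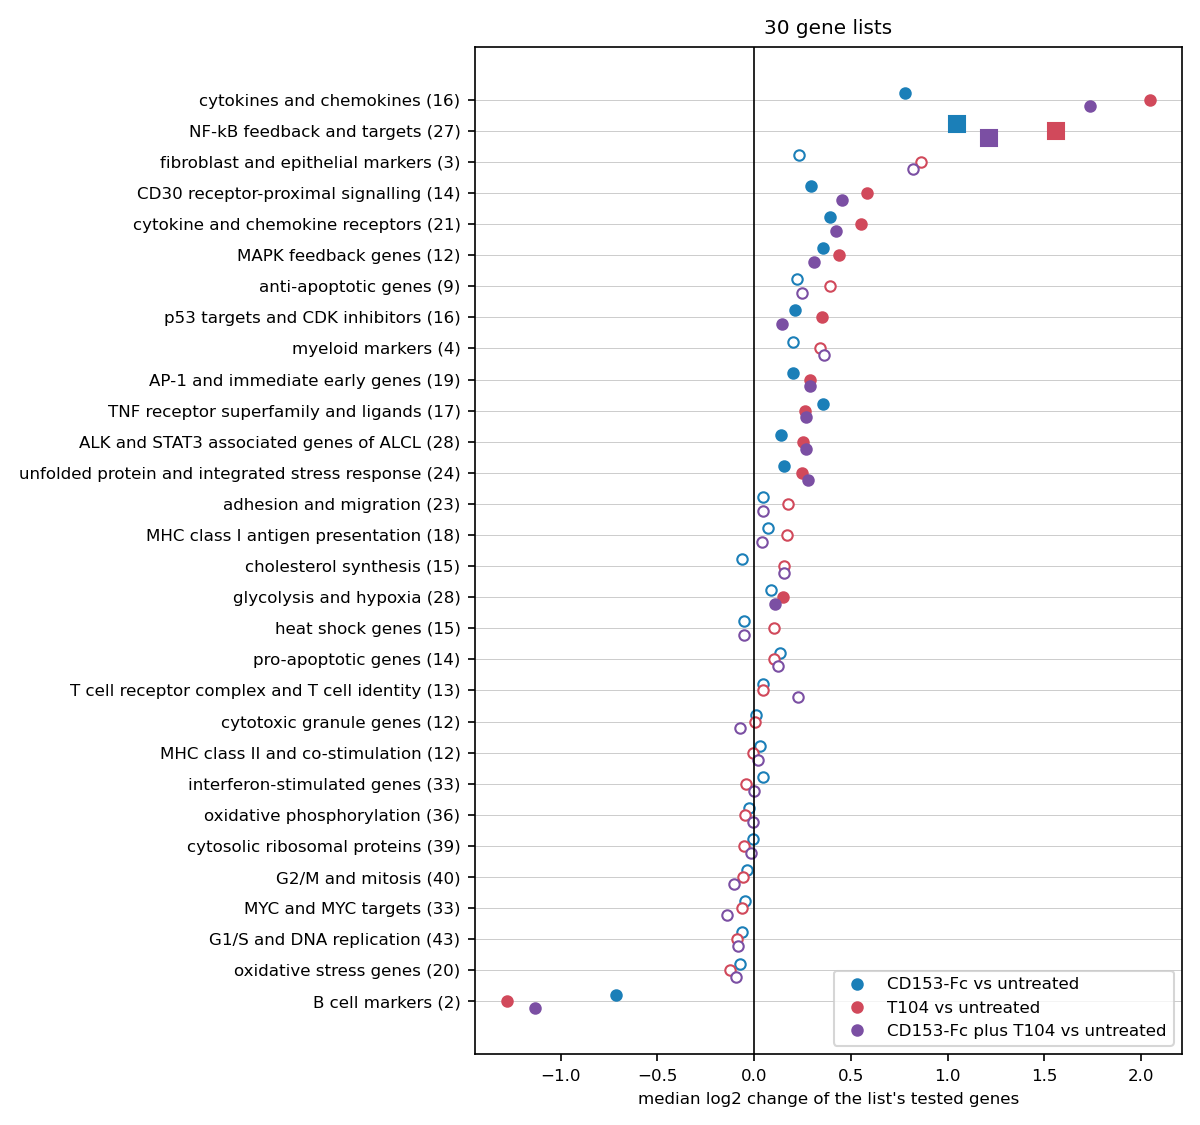
Median log2 change of each gene list's tested members against untreated cells, for CD153-Fc, T104 and both agents. Open symbols were not called by camera, filled circles were called with the preset correlation only, and squares were also called with an estimated correlation. The NF-kB list lay at 1.05, 1.56 and 1.21.

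T104 was set against CD153-Fc directly, at the same dose by weight and the same time. CCND2 was at least 9.10-fold higher with T104 (adjusted p = 1.57e-06), IL17F at least 3.12-fold, CCL20 5.84-fold (2.55 ± 0.23 log2), CXCL8 5.59-fold (2.48 ± 0.19) and LTA 4.43-fold (2.15 ± 0.31). KLHL14 was at least 1.24-fold lower with T104, and RAB27B (-1.41 ± 0.23), TNFRSF19 (-1.15 ± 0.16), BLK (-0.99 ± 0.19) and FYCO1, a gene of autophagosome transport (-0.89 ± 0.18), were lower too. These 5 lower calls were lost without each of the 4 arrays compared, and LTA's without 3 of them. Of the NF-kB genes 9 were higher, 19 when adjusted over the list alone, among them SOD2 (1.74 ± 0.16) and TRAF1 (1.11 ± 0.17), and the list was called (adjusted p = 3.22e-24, and adjusted p = 0.0420 with an estimated correlation). Of the cytokines 7 were higher, and 11 higher and 1 lower when adjusted over the list alone (adjusted p = 2.96e-14, and adjusted p = 0.0619 with an estimated correlation). NFKB2 (0.83 log2, 95% interval 0.29 to 1.37), CDKN1A (1.35, 0.67 to 2.04), RELB (0.44, 0.06 to 0.82) and CXCR4 (0.37, -0.08 to 0.82) were not called, and their intervals leave room for a difference. The 62 calls comprised 55 higher and 7 lower with T104. There were 17 without CD153-Fc replicate 1, 17 without its replicate 2, 11 without T104 replicate 1 and 10 without its replicate 2, and 412 in a model of these 2 groups alone, 452 with array weights and 41 among probes detected on all 8 arrays.

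Most genes that CD153-Fc raised were raised by T104 as well. Of the 112 features raised by CD153-Fc, 109 were also called higher with T104, and of the 28 lowered, 25 were called lower, against 5.72 and 1.52 for independent lists, and 0 were called in opposite directions. The changes correlated across the 10183 features, which are not independent replicates, at r = 0.838, where unchanged groups sharing the untreated arrays gave a mean of 0.783 and at most 0.795 in 100 simulations. The covariance was 0.134 against a simulated 0.0499, a difference of 0.0846, 80.5% of features had the same sign against 78.7%, and the simulations gave on average 0.02 features called in both against 134. The 2 untreated arrays were not split between the comparisons, so part of the excess may come from shared controls. Over the 679 features called with both agents together, the T104 change was 1.71 times the CD153-Fc change (slope, 1.60 to 1.78 with each array left out). T104 went further than CD153-Fc in 109 of the 112 features raised by CD153-Fc (medians 1.72 and 1.11 log2), and the T104 and CD153-Fc arrays differed over this set (fry adjusted p = 7.28e-04 over 2 tests). Among the 28 features lowered by CD153-Fc, T104 went further in 19, with medians of -0.91 log2 with T104 and -0.85 with CD153-Fc.

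**Figure D4:**
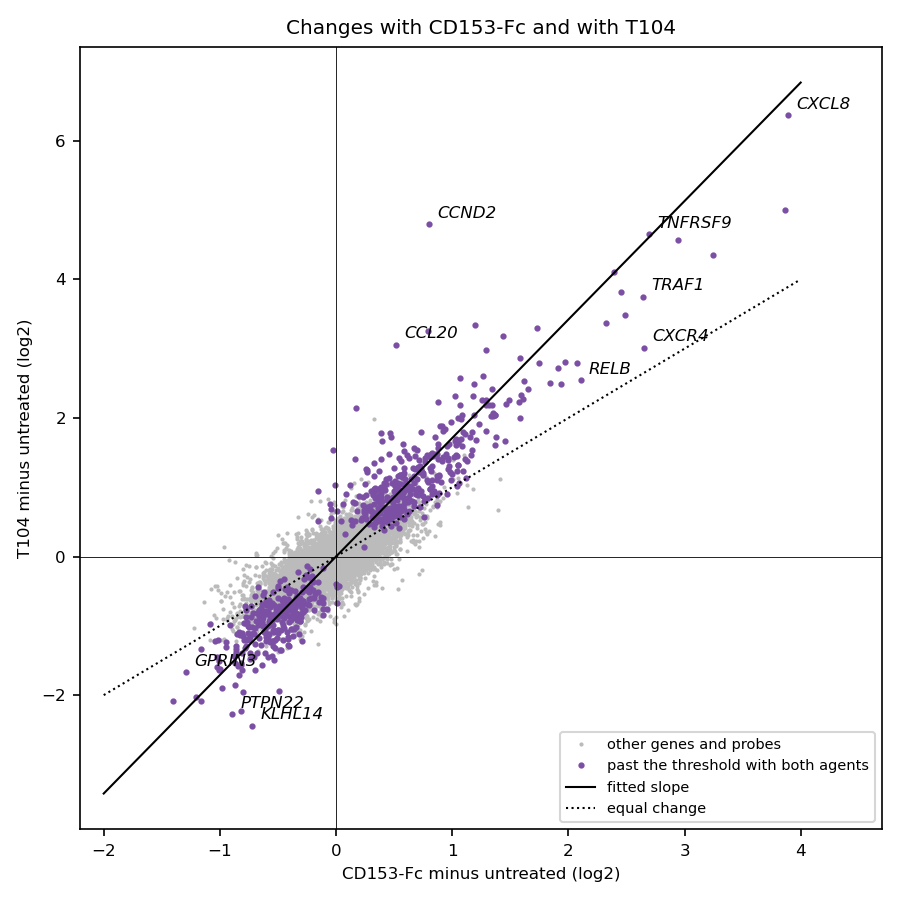
Change with T104 against change with CD153-Fc, both against untreated cells in log2, one point per feature. Purple points were called with the combination of both agents against untreated cells. The solid line is the slope of 1.71 and the dotted line marks equal change. CXCL8 lay at 3.89 with CD153-Fc and 6.37 with T104.

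Against CD153-Fc alone, the combination had higher CCND2 (at least 6.05-fold), IL17F (at least 2.42-fold), TNFRSF9 (1.84 ± 0.21 log2), CXCL8 (1.76 ± 0.19) and EBI3 (1.46 ± 0.19). All 19 calls were higher with the combination, and 0 were lower (limma, with 818 features of either direction at an unadjusted p under 0.05). Of the NF-kB genes 4 were higher (TRAF1, SOD2, DRAM1 and NINJ1) and 10 when adjusted over the list alone (adjusted p = 2.91e-12, and adjusted p = 0.0786 with an estimated correlation). CCND2 kept its call with each array left out, and the other 4 named genes lost theirs without at least 2 of the arrays. The count was 4 without CD153-Fc replicate 1, 7 without its replicate 2, and 1 without either replicate of the combination. There were 198 in a model of these 2 groups alone, 205 with array weights, 9 with median scaling, 9 among probes detected on all 8 arrays and 11 without a trend in eBayes.

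Against T104 alone, the combination gave 0 calls by limma, with 418 features at an unadjusted p under 0.05 and a smallest adjusted p of 0.352. Those 418 are below the share of 0.05 of the 10183 features that unchanged groups would give. The 3 named genes with the smallest p were DMC1, a meiotic recombinase gene (0.87 log2, 95% interval 0.56 to 1.18), CCL20 (-1.26, -1.76 to -0.76) and ZNF486 (0.67, 0.40 to 0.94). CXCL8 was at -0.72 (-1.14 to -0.31), CCND2 at -0.59 (-1.06 to -0.11), TRAF1 at -0.06 (-0.43 to 0.31) and TNFRSF9 at -0.12 (-0.58 to 0.35). The NF-kB list lay lower with the combination (median -0.29 log2, adjusted p = 7.74e-08), with adjusted p = 0.331 with an estimated correlation, and 0 of its members passed over all features. A model of these 2 groups alone gave 30 calls and array weights 56. Over the 112 features raised by CD153-Fc, the combination lay above T104 in 15, between the single agents in 92, and at a median of -0.23 log2 relative to T104 (fry adjusted p = 0.0232 over 2 tests). Over the 28 features lowered by CD153-Fc, the combination lay above T104 in 24 and between the single agents in 8, with a median of 0.32 log2 relative to T104. Over the 140 features called with CD153-Fc, the change with both agents was 0.889 times that with T104 (slope).

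The interaction tested whether the response to both agents differed from the sum of the single responses. CXCL8 was below the sum (-4.62 ± 0.27 log2, adjusted p = 1.79e-06), and so were DRAM1 (-2.91 ± 0.22), CXCR4 (-2.87 ± 0.29), RGS1 (-2.86 ± 0.24) and IL4I1, whose untreated level was not above background (at or below -2.01 log2 with that level at the detection limit). Of the NF-kB genes 15 were below the sum, 21 when adjusted over the list alone (median -1.29 log2, adjusted p = 2.71e-29, and adjusted p = 0.0291 with an estimated correlation). MBTD1 exceeded the sum by 1.86 ± 0.34 log2, the DNA repair gene XRCC2 by 1.56 ± 0.29, the TNF family ligand gene TNFSF15 by 1.498 ± 0.31 and CCBE1, a gene of lymphatic development, by 1.48 ± 0.27. SMIM43 was called above the sum too, but was not above background with T104 or both agents, so its excess has no measured size. These 5 lost their calls without 5 or 6 of the 8 arrays. The 136 calls comprised 53 above and 83 below the sum. Median scaling gave 21 above and 53 below, no filter 83 calls, eBayes without a trend 90 and array weights 223. The count was 471 without untreated replicate 1 (236 above the sum) and 1722 without untreated replicate 2 (807 above). It was 36 and 34 without CD153-Fc replicate 1 and 2 (1 and 4 above), 26 and 28 without T104 replicate 1 and 2 (1 and 1 above), and 40 and 32 without replicate 1 and 2 of the combination (4 and 0 above), so few calls above the sum were left without any of the treated arrays.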

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

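The tests of the shortfall of the response to both agents were chosen after that result was seen. So was that of untreated replicate 1 for the genes lower with each agent alone, which took the place of a test on features chosen for the pattern, and the other tests of those genes were chosen before.

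The interaction of CD153-Fc and T104 passed in 136 features, a difference between the effect of T104 with and without CD153-Fc that was tested directly in limma. The largest shortfalls among named genes measured in all groups were CXCL8 (-4.62 log2), DRAM1 (-2.91), CXCR4 (-2.87) and RGS1 (-2.86), and that of IL4I1, not above background in untreated cells, was at or below -2.01, all genes that each agent raised. The largest excesses measured in all groups were MBTD1 (1.86), XRCC2 (1.56), TNFSF15 (1.498) and CCBE1 (1.48), genes lower with each agent.

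Over the features raised by CD153-Fc, the response to both agents lay below the sum of the single responses, and mostly below that to T104 alone. A ceiling of the array signal was excluded, because the median of both minus T104 was -0.19 log2 over the 63 genes raised by CD153-Fc whose T104 mean lay under 11 log2, well below the brightest probes. The median of both minus T104, which uses no untreated array, was -0.23 log2. Untreated replicate 1 therefore cannot account for the combination lying below T104. Whether that array adds to the shortfall from the sum was not settled. The median interaction was -1.29 log2 with untreated replicate 2 alone. A rise with CD153-Fc lowers the interaction, however, and the features were chosen for that rise on both untreated arrays. Quantile normalization was excluded, since median scaling gave a median of both minus T104 of -0.36 log2, against -0.11 over all features. For the features raised by CD153-Fc, a step that both agents share and that limits the response, such as the receptor, remains a candidate explanation, because 82.1% of the 112 features raised by CD153-Fc had a mean with both agents between those of the single agents. The 28 features lowered by CD153-Fc went the other way, with 28.6% between the single agents (95% interval 13.2% to 48.7%), 24 above T104, and medians of -0.44 log2 with both against -0.85 with CD153-Fc and -0.91 with T104, and they were too few to decide whether the same step limits them. The arrays hold no measure of receptor occupancy, so this stays a hypothesis.

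All 53 features above the sum were lower with each agent alone (medians -0.66 log2 with CD153-Fc and -0.81 with T104) and their median with both lay nearer the untreated level (-0.24), although BLK, DIS3L, PCDH18, SGSM1, SMIM43 and TNFRSF19 were lower with both than with CD153-Fc. In 44 of the 53 features all 4 untreated and combination arrays lay above all 4 single-agent arrays. The interaction rises with high untreated and combination levels and low single-agent levels. Both counts therefore follow in part from how the features were chosen. A technical factor that varies from array to array stays open. Over these features 1 of the 4 replicate pairs, the untreated one, had a median difference (0.11 log2) outside that of random lists, but limma chose the features for replicates that agree, so the agreement of the other pairs excludes nothing. An effect of untreated replicate 1 stays open too. When 53 features were chosen on that array and 1 array of each treated group, their median interaction was taken on the other 4 arrays. It ran from 0.28 to 0.68 log2 over the 8 possible splits, above random lists (at most 0.20) in each. These values go against that array as the whole cause for the features so chosen, but the bound of 0.3 set for excluding it was missed in 1 split. Between 6 and 14 of the 53 features chosen in a split belonged to the pattern, so the medians describe mostly other features and do not decide the question for the pattern itself. Calls made without that array cannot decide it either, since the pattern was chosen on the same remaining arrays. Array position or handling order that tracks the group cannot be told apart from treatment, because 0 columns of the deposited tables gave an order. The counts of this pattern are fragile, since without any of the treated arrays between 0 and 4 features were called above the sum, and a biological origin in the combined treatment was not tested.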

How the results depend on the processing

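Median scaling over the kept probes was the one setting chosen after the data were seen, and its counts stayed within 1.5 times the main ones. Of 140 calls of named genes, 99 held in every setting that tested the gene, apart from leaving out an array. Of the 140, 82 held with each array left out, 82 held in both ways, and 0 reversed. Genes not detected on every array were not tested where probes had to be detected on every array. For these genes that setting was not counted as a loss. A call was tested only without the arrays of the groups in its contrast. The cause was not tested for the differences below unless stated.

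Median scaling gave 90 calls for CD153-Fc against untreated, 1638 for both agents against untreated, 9 for both against CD153-Fc and 74 for the interaction. Without a filter on dim probes there were 92 calls for CD153-Fc and 83 for the interaction, and r between the CD153-Fc and T104 responses was 0.728. Restriction to probes detected on all 8 arrays gave 41 calls for T104 against CD153-Fc and 9 for both against CD153-Fc. Without a trend in eBayes there were 11 for both against CD153-Fc and 90 for the interaction. Array weights gave 378 calls for both against untreated, 452 for T104 against CD153-Fc, 205 for both against CD153-Fc, 56 for both against T104 and 223 for the interaction. A model of the 2 groups compared gave 33 for CD153-Fc, 399 for T104 and 180 for both against untreated, 412 for T104 against CD153-Fc, and 198 and 30 for both against CD153-Fc and T104. By construction such a model leaves out the wider spread of the untreated pair where untreated cells are not compared. An estimated correlation between genes left 5 list calls of 67.

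With each array left out in turn, counts ran from 37 to 2624 for CD153-Fc, 286 to 3419 for T104 and 188 to 3345 for both against untreated. They ran from 10 to 17 for T104 against CD153-Fc, 1 to 7 for both against CD153-Fc, and 26 to 1722 for the interaction, and were 0 throughout for both against T104. The r between responses ran from 0.769 to 0.892 and list calls from 51 to 69. In these models the lone array of a group is assumed to vary like the other groups, and the highest counts against untreated cells and for the interaction came without untreated replicate 2.

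A replicate block gave 88 calls for CD153-Fc against untreated and stayed within 1.5 times the main count in the other comparisons. Deviations of equally numbered arrays from their group means correlated between -0.0987 and 0.00719 across features, which gave no sign of a strong shared effect. This does not settle whether equally numbered arrays were handled together. A slide block was not run, because no slide was used here as a label. Signal over background limits TNFRSF8 and the genes given as "at least" a fold.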

Other observations

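The test of a common factor was chosen after the result was seen, and that of weak signals near background before, although it was read as undecided after its value was seen, since a pair of features cannot decide it.

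Of 28 glycolysis and hypoxia genes, 7 rose with T104 and 8 with both agents, and 8 and 10 when adjusted over the list alone. VEGFA, the angiogenic factor, rose by 1.69 ± 0.36 log2 with T104 and by 1.79 ± 0.36 with both, and PFKFB4, a regulator of glycolytic flux, by 1.20 ± 0.22 and 1.30 ± 0.22. The untreated arrays differed in both genes, and without untreated replicate 1 the rises with T104 were 0.90 and 0.76 log2. The list was called with T104 (camera adjusted p = 0.0133, and adjusted p = 0.105 with an estimated correlation) and with both (adjusted p = 0.00642, and adjusted p = 0.101 with an estimated correlation). With CD153-Fc 0 passed in limma, 7 were at an unadjusted p under 0.05 (fry adjusted p = 0.01004), and 1 rose when adjusted over the list alone. Of 24 genes of the unfolded protein and integrated stress response, 5 rose and 1 fell with T104, 8 and 1 when adjusted over the list alone, and ATF3 (1.80 ± 0.17) and the phosphatase subunit gene PPP1R15A (0.87 ± 0.19) led the rises while PSPH fell (-0.68 ± 0.16). That list was called (adjusted p = 0.00686, and adjusted p = 0.105 with an estimated correlation), as it was with both agents (3 rises, 4 when adjusted over the list alone, adjusted p = 0.00197, and adjusted p = 0.0888 with an estimated correlation). With CD153-Fc it was called too (adjusted p = 0.0410, and adjusted p = 0.180 with an estimated correlation), where 0 passed in limma, 3 were at an unadjusted p under 0.05 and 1 rose when adjusted over the list alone. Of 15 heat shock genes, DNAJA1 alone rose with T104 (0.46 ± 0.12), also when adjusted over the list alone, and of 20 oxidative stress genes SOD2 alone, with all 3 treatments, also when adjusted over the list alone (list adjusted p = 0.374 and 0.707 with T104). VEGFA, PFKFB4, PPP1R15A and DNAJA1 lost their calls with T104 in at least 1 other setting, and without untreated replicate 1 PPP1R15A was at 0.55 and DNAJA1 at 0.30.

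Of 23 adhesion and migration genes, 4 rose and 2 fell with T104, 6 and 2 when adjusted over the list alone (list adjusted p = 0.212). The tetraspanin gene CD82 rose by 1.57 ± 0.20 log2 (1.02 without background correction) and the intermediate filament gene VIM by 1.20 ± 0.18, while the integrin genes ITGAL, which encodes the alpha chain of LFA-1 (-1.21 ± 0.18), and ITGA4 (-0.84 ± 0.18) fell. With CD153-Fc 0 passed in limma or adjusted over the list alone, and 5 were at an unadjusted p under 0.05 (fry adjusted p = 0.401). Of 15 cholesterol synthesis genes, HMGCS1 rose (0.77 ± 0.13) and HSD17B7 fell (-0.85 ± 0.15) with T104, 1 and 2 when adjusted over the list alone (list adjusted p = 0.407). HSD17B7 also fell with CD153-Fc (-0.70 ± 0.15), a call lost in 5 other settings, with 1 rise and 1 fall when adjusted over the list alone (list adjusted p = 0.811).

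Over the features called with both agents together T104 went further than CD153-Fc by a slope of 1.71, and the question was whether the excess differed between genes. One common factor for all genes remained open as the explanation, because 2 of the 10183 features departed from the slope times the CD153-Fc change at an adjusted p under 0.05. These were CCND2, above the slope but not above background in untreated cells or with CD153-Fc, and 1 unnamed probe (-1.61 log2, adjusted p = 0.0486). Compression of weak signals near background could not be decided, since 1 of the 2 was detected on both untreated arrays, and CCND2, undetected there, may depart for this reason alone. Few departures can be called with 2 arrays per group, so their small number does not establish a common factor. Features raised by CD153-Fc had medians of 1.11 log2 with CD153-Fc and 1.72 with T104. The 28 lowered had -0.85 and -0.91, closer together than the slope would give. Both sets were chosen on their CD153-Fc change.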
